A study of Homo sapiens with 27 samples.

How the data were processed

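The samples are 27 QuantSeq 3' RNA-seq libraries of teloHAEC, sequenced single-end for 86 cycles per the labels, in 6 groups over 2 experiment sets. The authors deposited a table of integer read counts per gene, 14008 genes by 27 libraries, and every count column was used (0 were not). The submitters' processing notes name edgeR 3.24.3 and the genome build hg38; the aligner and the counting program are not given in the sources used here. Ensembl gene IDs were matched to current symbols for 13053 genes and through GENCODE 29 for 861 more, and 94 had no symbol. Positions on GRCh38 were found for 13899 and not for 109.

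Total counts per library ranged from 3.43 to 7.75 M (mega). A count of 0 allows a level of up to 0.387 to 0.875 CPM, taking 3 counts of the library's total. Reads carry no molecular identifiers, so such limits cover counting error only. The SE of a log2 fold change was taken as its size divided by the square root of the F statistic of the edgeR test. The intervals use this SE with the t distribution. They include the spread between libraries and are approximate, above all for genes with low counts. Libraries of a group differed by a chi-square per degree of freedom of 3.03 to 78.9, so none was a copy of another. The labels give replicate numbers in accession order and pair no libraries. The labels number SMAD3 deletion libraries 10 to 13 and the controls of set A 26 to 33, and LDAH deletion libraries 50 to 54 and the controls of set B 55 to 67; the labels do not say what the number means, so any difference in handling that follows it cannot be told apart from the deletions. The numbers of HPRT-targeted and negative control libraries alternate from 26 to 33 in set A and mostly in set B.

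Counts were analysed with edgeR 4.0.16 in R 4.3.3: TMM normalisation, genes kept by filterByExpr with the group, a quasi-likelihood fit of group means and its two-sided test, and Benjamini-Hochberg adjustment over all genes tested at 0.05. The fits held the 12 libraries of set A (11467 genes), the 15 of set B (11769), the 19 negative control and HPRT-targeted libraries of both sets with the set as a covariate (11836), or all 27 (12055, for differences between effects). The common dispersion was 0.0434 in set A and 0.195 in set B. There were 9 comparisons: each deletion and each HPRT-targeted group against the negative control of its set, each deletion against the HPRT-targeted group, HPRT targeting in both sets, and the differences of the HPRT and of the deletion effects. CPM, scaled by the TMM factors, are given as mean ± SD, and log2 fold changes with their SE. For the target genes, log2 CPM with a prior count of 2 were compared by a two-sided exact permutation test.

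The 16 gene lists were written before the data were examined: p53 targets, TGF-beta and SMAD3 targets, TGF-beta and BMP pathway components, interferon-stimulated genes, NF-kB and endothelial inflammatory genes, endothelial identity, mesenchymal markers, epithelial and blood cell markers, proliferation, cholesterol synthesis and uptake, lipid droplet proteins and lipases, integrated stress and unfolded protein response, heat shock, hypoxia and glycolysis, purine salvage and synthesis, and mitochondrially encoded genes. They were tested with camera of limma 3.58.1 on voom log2 CPM with a preset correlation of 0.01, adjusted over the 16 lists of a comparison. The alternative with an estimated correlation used voom log2 CPM without precision weights. With weights, the estimate depended on the order of the design's columns and on the processor, so this change was made after seeing the data. It moved 1 call, that of proliferation genes for HPRT targeting in both sets without the 7 libraries that stand apart, which passed with weights and did not without them. An exact permutation of each list's mean over libraries was added after seeing the data; with 4 libraries against 4 its smallest p, 0.0286, passes the adjustment only if most of the 16 lists reach it together.

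The comparisons, tests, gene lists, alternatives and the rule for naming genes were chosen before the data were examined. The rule names SMAD3, LDAH and HPRT1; the nearest 2 neighbours of each target and near genes with an unadjusted p under 0.05; up to 10 called genes per direction with the largest changes and a mean CPM of at least 10; and the 4 members with the smallest p of each list that passed. The rule was applied in the same way to calls without the 7 libraries that stand apart. Any other gene whose value is given is said to be named after its values were seen. Alternatives were DESeq2 1.42.0, limma voom with sample quality weights, DESeq2's size factors within edgeR, no filter, a filter at a mean CPM of 10, thinning of all libraries to a common total, only the compared groups or all 27 libraries in the fit, a pooled control, windows of 0.5 and 2 Mb, and leaving out each library in turn. Leaving out the 7 libraries whose median correlation lay more than 3 scaled median absolute deviations under the median of their set was added after seeing the data. It leaves 10 libraries in each set. A block for HPRT-targeted and negative control libraries whose numbers follow each other, 4 pairs in each set, was added after seeing the data too. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

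Recovery was tested on simulated data with the libraries' own totals and dispersions and 200 changed genes. The edgeR test found 14.9%, 59.7% and 93.9% of genes changed 1.5, 2 and 4 fold for the SMAD3 deletion against its negative control, and 2.99%, 10.4% and 66.7% for the LDAH deletion. For HPRT targeting it found 10.4%, 74.6% and 93.9% in set A, 1.49%, 16.4% and 66.7% in set B, and 23.9%, 64.2% and 100% in both sets. Against HPRT-targeted libraries it found 20.9%, 58.2% and 93.9% for the SMAD3 deletion and 0%, 4.48% and 60.6% for the LDAH deletion. For the differences it found 0%, 7.46% and 47.0% (HPRT effects) and 1.49%, 4.48% and 45.5% (deletion effects). False calls numbered 0 to 8 per comparison. Camera called a list raised 1.25 fold in all 9 comparisons and 0 of 16 unchanged lists. Genes were simulated independently of each other and the unchanged lists were random genes. The simulation therefore does not measure camera's false calls where members of a list vary together. It also holds no shift shared across genes like that of the 7 libraries that stand apart. With 200 changed genes the Benjamini-Hochberg adjustment is less strict than in a fit with few changes. The rates may therefore overstate the recovery of a single changed gene.

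The positions of the deleted enhancers are not in the labels, so distances are from the gene and the deleted interval is not analysed here. Genes without a symbol were passed over in naming. DPH1 and OVCA2, and ASDURF and ASNSD1, overlap; MTRNR2L8 and MTRNR2L12 are copies of MT-RNR2; no fold is given for MATR3 (ENSG00000280987), PTP4A1 and AC020978.7, whose values rest on libraries with a count of 0.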

Results

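The libraries measured messenger RNA 3' ends in teloHAEC, an immortalised line of human aortic endothelial cells, 2 days after electroporation of Cas9 ribonucleoprotein into 150000 cells per replicate. In the deletion groups, guide RNAs flanked a candidate enhancer of SMAD3, which encodes a transcription factor of TGF-beta signalling, or of LDAH (earlier C2orf43), which encodes a lipid droplet associated hydrolase. A non-targeting guide served as the negative control. A guide against HPRT1, the gene of a purine salvage enzyme, served as the positive control and also cleaves the genome. The 27 libraries form 2 sets. Set A holds 4 SMAD3 deletion, 4 HPRT-targeted and 4 negative control libraries, and set B holds 4 LDAH deletion, 4 HPRT-targeted and 7 negative control libraries. Total counts ranged from 4.76 to 7.75 M in set A and from 3.43 to 6.41 M in set B. The labels do not say that replicates came from separate cultures beyond their electroporations, so the p-values measure the spread between these samples.

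In 7 libraries, expression across genes stood apart from the rest of the set: SMAD3 deletion replicate 4 and HPRT-targeted replicate 3 in set A, and LDAH deletion replicate 4, negative control replicates 6 and 7, and HPRT-targeted replicates 2 and 4 in set B. Their median correlation with the other libraries of the set was 0.885 to 0.945 in set A and 0.786 to 0.842 in set B, against 0.977 to 0.984 and 0.925 to 0.963 for the other libraries. Ribosomal protein genes took 14.6% to 15.7% of their counts in set A and 14.3% to 16.5% in set B, against 11.3% to 13.8% and 8.83% to 10.8%. Endothelial identity genes were lower in them, with a median log2 difference of -0.29 in set A and -0.49 in set B. The mesenchymal markers were lower too, by medians of -0.38 and -0.60, while interferon-stimulated genes were higher, by 0.20 and 0.25. The p53 targets were higher in them as well, by 0.14 and 0.20, as were cholesterol genes, by 0.17 and 0.32, and proliferation genes were at -0.06 and -0.04. Mitochondrially encoded genes were lower in them, by medians of -0.17 and -0.40. The libraries are spread over 5 of the 6 groups. Values without these 7 libraries come from an alternative chosen after seeing the data and are named as such.

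**Figure D1:**
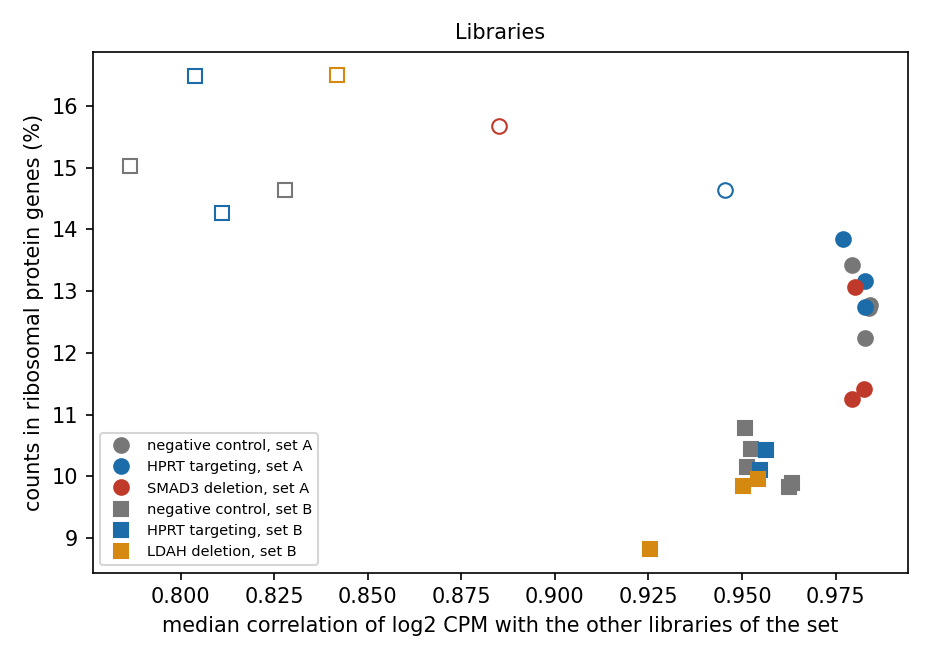
Each point is a library, placed by its median correlation of log2 CPM with the other libraries of its set (x axis) and its percent of counts in ribosomal protein genes (y axis), with colours and shapes for the 6 groups and open symbols for the 7 libraries that stand apart. The open symbols lie at 14.3% to 16.5%, above the other libraries at 8.83% to 13.8%.

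The first question is whether each target gene changed in the cells treated for it. SMAD3 (ENSG00000166949; chromosome 15, 67063763 to 67195195, GRCh38) stood at 94.8 ± 15.1 CPM (SD, n = 4) in the SMAD3 deletion libraries and 128 ± 9.21 CPM (n = 4) in the negative control of set A. Every deletion library, at 72.4 to 105 CPM, lay below every control library, at 116 to 136 CPM, and the exact permutation p was 0.0286, the smallest that 70 arrangements allow. The log2 fold change was -0.44 ± 0.14 (SE), with a 95% interval from -0.74 to -0.13. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes, the adjusted p was 0.702. The fold change was -0.31 without SMAD3 deletion replicate 4, and -0.33 ± 0.10 without the 7 libraries. SMAD3 in the LDAH deletion was at 119 ± 18.1 CPM against 120.2 ± 26.8 CPM in its control, a log2 fold change of -0.01 ± 0.20.

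LDAH (ENSG00000118961; chromosome 2, 20684014 to 20823130) was a weakly expressed gene, at 7.32 ± 3.44 CPM (n = 4) in the LDAH deletion and 12.5 ± 3.61 CPM (n = 7) in the negative control of set B. The log2 fold change was -0.76 ± 0.40, the exact permutation p was 0.0303 over 330 arrangements, and the adjusted p of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 1.00. All 4 deletion libraries lay below the control mean, and their counts of LDAH were between 9 and 61. Leaving out LDAH deletion replicate 4 gave -0.50, and leaving out the 7 libraries gave -0.51 ± 0.34. In the SMAD3 deletion, LDAH had a log2 fold change of -0.15 ± 0.19.

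HPRT1 (ENSG00000165704; chromosome X, 134460153 to 134520513) stood at 32.4 ± 6.57 CPM (n = 4) in HPRT-targeted and 40.9 ± 8.12 CPM (n = 4) in negative control libraries of set A, a log2 fold change of -0.33 ± 0.21 with an exact permutation p of 0.114. In set B the levels were 43.2 ± 13.2 CPM (n = 4) and 50.9 ± 21.9 CPM (n = 7), a log2 fold change of -0.23 ± 0.33 with an exact permutation p of 0.545. The value of set A was -0.48 without HPRT-targeted replicate 3, and that of set B was -0.00 without negative control replicate 7. Without the 7 libraries that stand apart, the values were -0.48 ± 0.14 in set A and -0.21 ± 0.24 in set B. Each of these 7 libraries had more HPRT1 than the libraries of its group that do not stand apart. Adjusted over the 4 target tests, the permutation p-values were 0.0606 for SMAD3, 0.0606 for LDAH, 0.152 for HPRT1 in set A and 0.545 in set B. The labels do not give the deleted intervals, and whether these hold part of a transcript was not analysed here. A guide that leaves small insertions or deletions in HPRT1 need not lower its 3' tags, so these levels do not measure how many cells were edited.

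**Figure D2:**
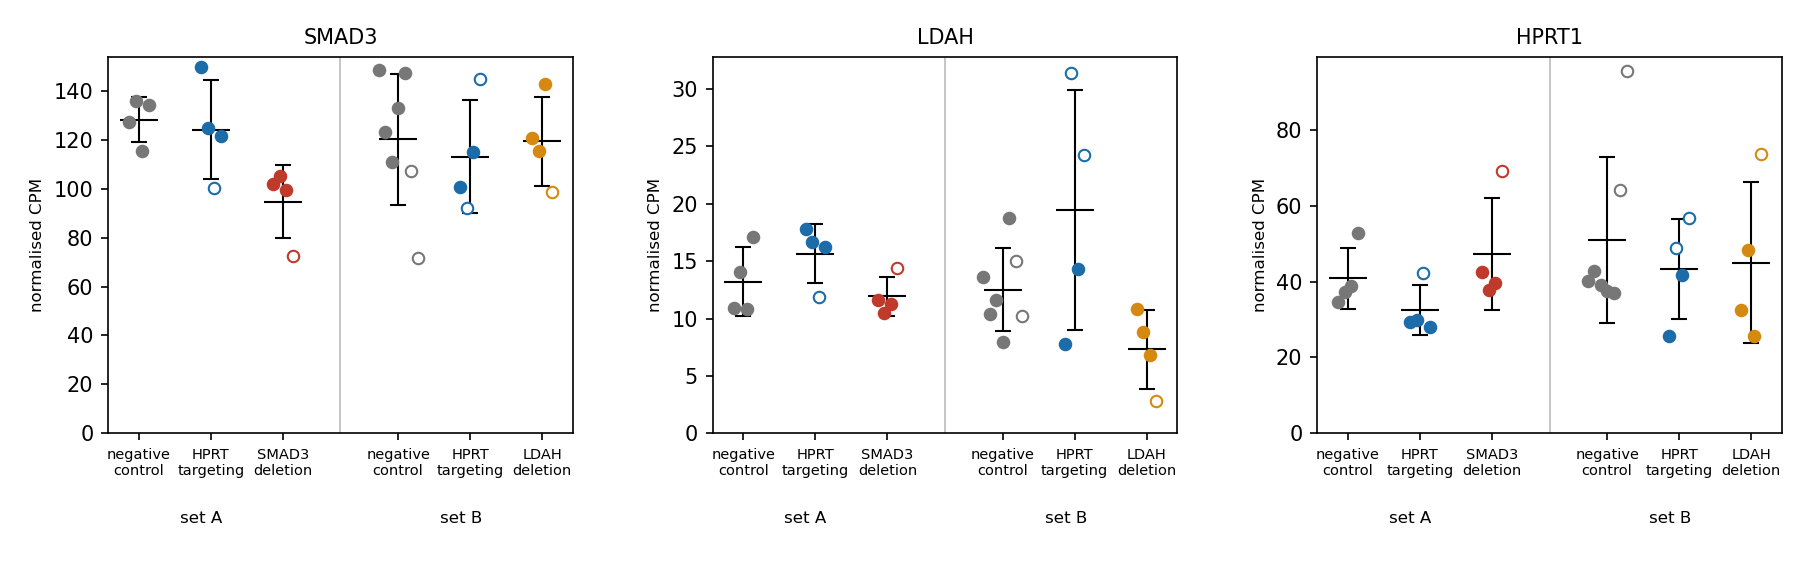
Normalised CPM of SMAD3, LDAH and HPRT1 in each library by group, with bars for the mean ± SD and open symbols for the 7 libraries that stand apart. The 4 SMAD3 deletion libraries lie at 72.4 to 105 CPM of SMAD3, below the 4 control libraries at 116 to 136 CPM.

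The neighbours of each target, within 1 Mb of its annotated span, show whether a change extends along the chromosome. Around SMAD3, 12 genes were tested, 3 higher and 9 lower, with log2 fold changes from -0.27 to 0.25. AAGAB, which encodes a chaperone of clathrin adaptor complexes and lies 5838 bp from SMAD3, was at 82.2 ± 27.1 CPM (n = 4) against 98.6 ± 6.18 CPM (n = 4), a log2 fold change of -0.27 ± 0.18. Without SMAD3 deletion replicate 4 it was -0.49, with an edgeR p of 0.0118 adjusted over the near genes alone, and with the 7 libraries left out it was -0.51 with 0.00278. SMAD6, an inhibitor of BMP signalling, had -0.05 ± 0.28. Around LDAH, 9 genes were tested. HS1BP3 had a log2 fold change of -0.01 ± 0.34, APOB, the lipoprotein gene, had 1.37 ± 1.19 at 2.13 against 0.814 CPM, and MATN3, a matrix protein gene, had -1.99 ± 0.91 at 0.891 against 3.75 CPM. MATN3 was the only gene of the 9 with an unadjusted p under 0.05, and its edgeR p adjusted over the near genes alone was 0.377. Around HPRT1, PHF6, a chromatin protein gene, had -0.21 ± 0.11 in set A and 0.31 ± 0.20 in set B, and PABIR2 had -0.23 ± 0.18 and -0.46 ± 0.33, the latter being -0.81 ± 0.36 without the 7 libraries. Without negative control replicate 1, ZNF449 in set A, named after its values were seen, had -1.29, with an edgeR p of 0.0435 adjusted over the near genes alone. With all libraries, edgeR's quasi-likelihood test passed 0 near genes in windows of 0.5, 1 and 2 Mb, over all genes and over the near genes alone; limma voom with sample quality weights passed AAGAB (-0.49, adjusted p = 0.00625 over the near genes alone) and PHF6 in set A (-0.29, 0.0409).

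**Figure D3:**
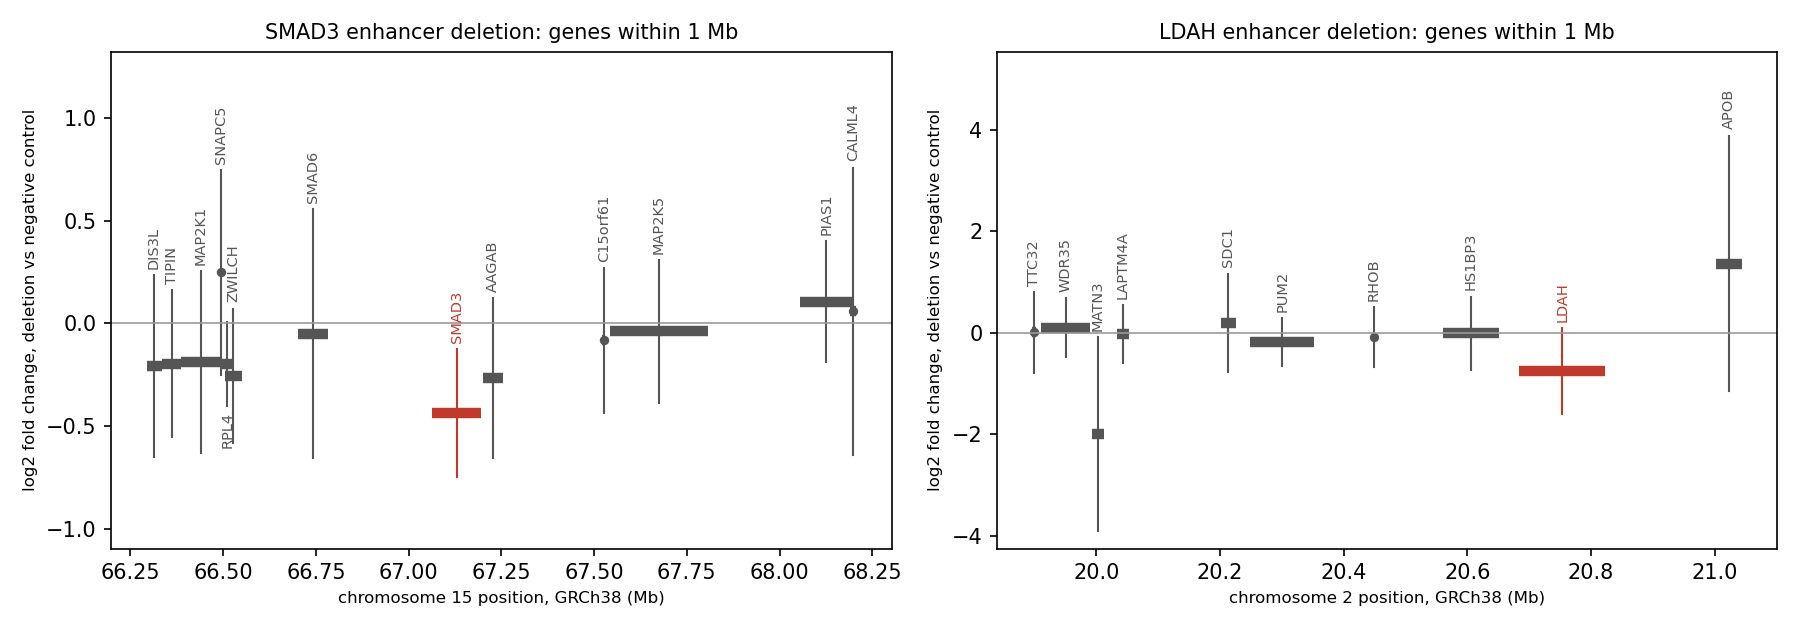
Log2 fold change of deletion against negative control (y axis) for SMAD3 and LDAH, in red, and the tested genes within 1 Mb, against position on GRCh38 (x axis, Mb); horizontal bars span each gene, short genes are points, and vertical lines are 95% intervals. The 12 genes around SMAD3 lie between -0.27 and 0.25, and SMAD3 itself is at -0.44.

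Targeting of HPRT against the non-targeting control asks what a guide that cleaves the genome does to these cells. The guide also targets HPRT1, so effects of cleavage, of a disrupted HPRT1 and of this guide cannot be told apart here. Across both sets, with the set as a covariate, p53 target genes rose as a group. Of 34 members, 29 were higher in the 8 HPRT-targeted than in the 11 negative control libraries, with a median log2 fold change of 0.21 and a camera adjusted p of 5.8e-11 from limma. The call held with an estimated correlation (adjusted p = 0.00185) and in an exact permutation of the list's mean within sets, with p = 0.000216 and an adjusted p of 0.00346 over 23100 arrangements. MDM2 (ENSG00000135679), whose product degrades p53, had a log2 fold change of 0.53 ± 0.12, and CDKN1A (ENSG00000124762), the p21 inhibitor of the cell cycle, had 0.51 ± 0.14. GDF15, a stress-induced secreted factor, had 0.32 ± 0.09, and RRM2B, a ribonucleotide reductase subunit induced by p53, had 0.34 ± 0.13. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 members passed over all genes and 3 passed adjusted over the list alone, MDM2 (0.00658), CDKN1A (0.0238) and GDF15 (0.0238).

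Proliferation genes were lower in the same comparison, 30 of 36 members, with a median log2 fold change of -0.20 and a camera adjusted p of 2.0e-06, and adjusted p = 0.341 with an estimated correlation. HMGB2, a chromatin protein of dividing cells, had -0.49 ± 0.16, MCM6 of the replicative helicase had -0.31 ± 0.12, NUSAP1 of the spindle had -0.26 ± 0.10, and the topoisomerase gene TOP2A had -0.44 ± 0.19. The exact permutation of the list's mean gave an adjusted p of 0.224. Without the 7 libraries all 36 members were lower, 25 passed adjusted over the list alone, and the adjusted p was 5.9e-31 with camera, 0.0812 with an estimated correlation and 0.0145 in the exact permutation. In the same fit 31 of 34 p53 targets were higher and 8 passed adjusted over the list alone, with a camera adjusted p of 6.4e-13, and 0.0114 with an estimated correlation. The other 14 lists did not pass with all libraries, hypoxia and glycolysis genes coming nearest at a camera adjusted p of 0.0516.

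Gene by gene, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 11836 genes for HPRT targeting in both sets. An unadjusted p under 0.05 was reached by 378 genes, 214 higher and 164 lower, where 592 would come by chance. With 1 library left out, this number ran from 274 (HPRT-targeted replicate 4 of set B) to 774 (negative control replicate 7 of set B). DESeq2 called 1 gene. Limma voom with sample quality weights called 6 genes, 3 higher, among them CDKN1A and GASK1B, and 3 lower (TMPO, SGO1 and HMGB2), and edgeR without the 7 libraries called GASK1B (0.69, adjusted p = 0.0451), which had 0.17 with all libraries (edgeR adjusted p = 0.946). These genes, apart from CDKN1A and HMGB2, were chosen after their values were seen.

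Within set A, 30 of 34 p53 targets were higher in HPRT-targeted libraries (n = 4 and 4), with a median of 0.19 and a camera adjusted p of 1.9e-08, and adjusted p = 0.238 with an estimated correlation. CDKN1A stood at 483 ± 79.6 against 318 ± 66.8 CPM (0.60 ± 0.19), MDM2 had 0.39 ± 0.16, RRM2B 0.47 ± 0.19, and FDXR, a mitochondrial reductase gene, 0.41 ± 0.18. Proliferation genes were lower in 34 of 36 members, with a median of -0.20 and a camera adjusted p of 1.9e-08, and adjusted p = 0.452 with an estimated correlation. HMGB2 had -0.52 ± 0.18, the helicase gene MCM2 -0.38 ± 0.15, the transcription factor gene E2F1 -0.44 ± 0.18, and the replication licensing gene CDT1 -0.34 ± 0.15. Cholesterol synthesis and uptake genes were higher in 21 of 25, with a median of 0.08 and a camera adjusted p of 0.00845, and adjusted p = 0.452 with an estimated correlation. Their adjusted p was 0.0618 without negative control replicate 3. Among the enzyme genes of this list were PMVK (0.32 ± 0.14), SC5D (0.28 ± 0.13) and MVD (0.27 ± 0.16). In edgeR's test 0 members of these lists passed, over all genes or adjusted over the list alone. The purine genes, related to the enzyme's own pathway, had a camera adjusted p of 0.533. Over all 11467 genes edgeR called 0, with 257 at an unadjusted p under 0.05, while DESeq2 called 1, MATR3 (ENSG00000280987), limma voom with sample quality weights called 0, and edgeR without the 7 libraries called DPH1. Both were named after their values were seen, and DPH1 shares its locus with OVCA2, so its counts are uncertain.

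Within set B, 27 of 34 p53 targets were higher in HPRT-targeted libraries (n = 4 and 7), with a median of 0.24 and a camera adjusted p of 2.3e-06, and adjusted p = 0.122 with an estimated correlation. MDM2 stood at 248 ± 35.5 against 159 ± 29.5 CPM (0.64 ± 0.16) and was the 1 member past edgeR's test adjusted over the list alone (adjusted p = 0.0366), with 0 past it over all genes. GDF15 had 0.40 ± 0.15, the receptor gene EDA2R 0.52 ± 0.25 and the transcriptional regulator SERTAD1 0.57 ± 0.28, or 0.12 ± 0.25 without the 7 libraries. Proliferation genes were lower in 26 of 36 members, with a median of -0.19 and a camera adjusted p of 0.0360, and adjusted p = 0.976 with an estimated correlation. MCM6 had -0.36 ± 0.18, NUSAP1 -0.31 ± 0.16, HMGB2 -0.45 ± 0.25 and TOP2A -0.48 ± 0.34. The list's adjusted p was 0.797 without HPRT-targeted replicate 3, 0.120 without HPRT-targeted replicate 1, and 0.233, 0.210, 0.222 and 0.134 without negative control replicates 2, 4, 5 and 6. The purine genes had 0.950. Over all 11769 genes edgeR called 0, with 206 at an unadjusted p under 0.05, and DESeq2, limma voom with sample quality weights, and edgeR without the 7 libraries called 0 too. With 1 library left out, the number at an unadjusted p under 0.05 ran from 154 (negative control replicate 1) to 525 (HPRT-targeted replicate 3).

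**Figure D4:**
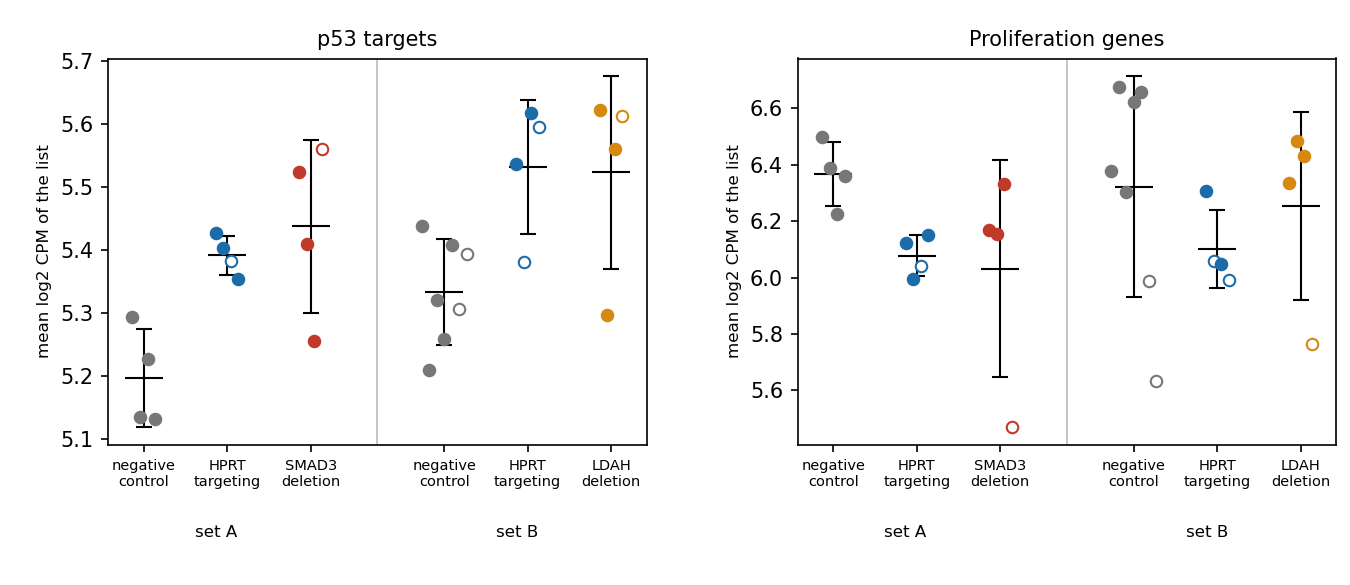
Mean log2 CPM of the 34 p53 targets and of the 36 proliferation genes in each library by group, with bars for the mean ± SD and open symbols for the 7 libraries that stand apart. The p53 score is 5.39 ± 0.03 in HPRT-targeted and 5.20 ± 0.08 in negative control libraries of set A, and 5.53 ± 0.11 and 5.33 ± 0.08 in set B.

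The SMAD3 enhancer deletion against the negative control of set A asks which genes respond to loss of the enhancer. The p53 targets were higher in 32 of 34 members (n = 4 and 4), with a median log2 fold change of 0.25 and a camera adjusted p of 1.9e-07, and adjusted p = 0.329 with an estimated correlation. FAS, a death receptor gene, had a log2 fold change of 0.82 ± 0.26, and MDM2 stood at 197 ± 29.9 against 140.1 ± 30.8 CPM (0.49 ± 0.16). RRM2B had 0.53 ± 0.19 and ASCC3, a DNA helicase gene, 0.36 ± 0.13. Proliferation genes were lower in 33 of 36 members, with a median of -0.29 and a camera adjusted p of 5.6e-09, and adjusted p = 0.662 with an estimated correlation. The helicase genes MCM7 and MCM5 had -0.44 ± 0.13 and -0.37 ± 0.13, the thymidylate synthase gene TYMS -0.31 ± 0.11, and the mitotic cyclin gene CCNB2 -0.43 ± 0.16. Interferon-stimulated genes were higher in 23 of 29, with a median of 0.17 and a camera adjusted p of 0.0147, and adjusted p = 0.505 with an estimated correlation. Their members IFIT5 (0.58 ± 0.23), ISG15 (0.75 ± 0.30), TRIM22 (0.67 ± 0.28) and IFI44L (1.54 ± 0.71) encode antiviral proteins. Without SMAD3 deletion replicate 4 the adjusted p was 0.0950, ISG15 was at 0.35, TRIM22 at 0.35 and IFI44L at 0.29. In edgeR's test 0 members of the 3 lists passed, over all genes or adjusted over the list alone.

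The targets of TGF-beta and SMAD3 themselves were divided, with 17 of 33 higher, a median of 0.02, a mean of -0.03 and a camera test pointing down at an adjusted p of 0.808. The same adjusted p of 0.808 held for TGF-beta and BMP pathway components, NF-kB genes, mesenchymal markers, epithelial and blood cell markers, cholesterol, heat shock, hypoxia and purine genes. For cholesterol, heat shock, hypoxia and purine genes the test pointed down while the medians, 0.02, 0.01, 0.01 and 0.02, were positive. The adjusted p was 0.604 for endothelial identity genes, 0.675 for lipid droplet genes (test up, median 0.05, mean -0.00), 0.289 for stress and unfolded protein response genes and 0.289 for mitochondrially encoded genes. The only member of these 13 lists past edgeR's test adjusted over the list alone was HSPE1, a mitochondrial chaperone gene, at -0.39, which was named after its values were seen.

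Over all 11467 genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 for the SMAD3 deletion, with a smallest adjusted p of 0.189. An unadjusted p under 0.05 was reached by 778 genes, 464 higher and 314 lower, where 573 would come by chance. With 1 library left out, this number ran from 518 (negative control replicate 2) to 1050 (SMAD3 deletion replicate 2). DESeq2 called 14, 6 higher and 8 lower, and limma voom with sample quality weights called MTRNR2L8 and ASDURF. MTRNR2L8 (ENSG00000255823), a nuclear copy of the mitochondrial ribosomal RNA gene whose reads cannot be fully separated from it, stood at 1081 ± 196 CPM (n = 3) against 454 ± 128 CPM (n = 4) without the 7 libraries. Its log2 fold change there was 1.25 ± 0.17 with an edgeR adjusted p of 0.00452, the only call of that fit. MTRNR2L8 also differed between the sets, at 3002 CPM in the negative control of set B (n = 5). Without the 7 libraries, the deletion's fold changes correlated across genes with those between HPRT-targeted libraries of set B and set A (Pearson r = 0.34). This test was chosen after seeing the data. A technical difference like that between the sets is not excluded for this call. ASDURF, named after its values were seen, overlaps ASNSD1, so its counts are uncertain. Mitochondrially encoded genes were lower by camera without the 7 libraries (adjusted p = 4.7e-08, and 0.388 with an estimated correlation).

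The LDAH enhancer deletion against the negative control of set B poses the same question for the other locus. The p53 targets were higher in 25 of 34 members (n = 4 and 7), with a median log2 fold change of 0.26 and a camera adjusted p of 0.00360, and adjusted p = 0.250 with an estimated correlation. MDM2 stood at 254 ± 34.3 against 159 ± 29.5 CPM (0.68 ± 0.16) and passed edgeR's test adjusted over the list alone (adjusted p = 0.0229). CDKN1A had 0.54 ± 0.22, the apoptosis gene BAX 0.57 ± 0.24, and SUSD6, against the direction of the list, -0.65 ± 0.20. The list's adjusted p was 0.145 without LDAH deletion replicate 4. Genes of the integrated stress and unfolded protein response were lower in 24 of 31, with a median of -0.30 and a camera adjusted p of 0.00180, and adjusted p = 0.415 with an estimated correlation. EDEM1, of protein degradation from the endoplasmic reticulum, had -0.90 ± 0.25, the secreted stress protein gene MANF -0.71 ± 0.25, the transcription factor gene CEBPB -1.24 ± 0.46 and the amino acid transporter gene SLC3A2 -0.39 ± 0.16.

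Mitochondrially encoded genes were higher in 13 of 13 in the LDAH deletion, with a median of 0.25 and a camera adjusted p of 0.00352, and adjusted p = 0.415 with an estimated correlation. MT-ND2 and MT-ND5 of complex I had 0.42 ± 0.18 and 0.64 ± 0.31, MT-ATP8 of ATP synthase 0.71 ± 0.46 and MT-CO3 of cytochrome oxidase 0.28 ± 0.20. The adjusted p was 0.0582 without LDAH deletion replicate 1. The 6 epithelial and blood cell markers measured were all higher, with a median of 0.20 and a camera adjusted p of 0.0163, and adjusted p = 0.250 with an estimated correlation. These were led by KRT7 (1.12 ± 0.55) and CD14 (2.04 ± 1.07, or 3.06 ± 1.18 without the 7 libraries), with KRT18 at 0.15 ± 0.14 and KRT19 at 0.22 ± 0.25, or -0.15 without LDAH deletion replicate 4. The adjusted p was 0.3003 without LDAH deletion replicate 4 and 0.104 without negative control replicate 2. The 5 libraries of set B that stand apart also had higher epithelial and blood cell markers, by a median of 0.38.

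The other 12 lists did not pass in the LDAH deletion. Camera adjusted p-values were 0.104 for proliferation, 0.135 for cholesterol, 0.153 for NF-kB, 0.243 for mesenchymal markers, 0.498 for interferon-stimulated, endothelial identity and purine genes, and 0.559 for the lipid droplet proteins and lipases that LDAH works among. They were 0.784 for TGF-beta and BMP components, 0.853 for heat shock genes, 0.881 for hypoxia genes, and 0.853 for TGF-beta and SMAD3 targets, whose median was 0.12, mean -0.05 and test down. Adjusted over the list alone, edgeR's test passed 4 members of these lists, all named after their values were seen. KLF2, a flow-induced transcription factor gene of endothelium, had -1.49 and EGFL7, a secreted vascular factor gene, had 0.78. CCN1, a matrix signalling gene, had -0.89, and SNAI1, a regulator of mesenchymal change, had -1.58.

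Over all 11769 genes edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 for the LDAH deletion, with a smallest adjusted p of 0.693. An unadjusted p under 0.05 was reached by 543 genes, 151 higher and 392 lower, where 588 would come by chance. With 1 library left out, this number ran from 344 (LDAH deletion replicate 3) to 957 (LDAH deletion replicate 4). DESeq2 called 14, all lower, among them KLF2 (-1.48), MYC (-1.37) and EFNB1 (-0.80), limma voom with sample quality weights called 0, and a fit of all 27 libraries called 9. Leaving out LDAH deletion replicate 4 gave 3 calls, KLF2 (-2.08), CD9 (-2.44) and PPP4C (-3.67). These genes were chosen after their values were seen.

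Without the 7 libraries, with 3 deletion and 5 control libraries left, edgeR called 212 genes in the LDAH deletion, 21 higher and 191 lower. KLF2 (ENSG00000127528) stood at 15.03 ± 2.85 CPM (n = 3) against 65.9 ± 19.0 CPM (n = 5), a log2 fold change of -2.13 ± 0.24 with an adjusted p of 2.4e-05. CD9, which encodes a membrane tetraspanin, stood at 67.04 ± 30.3 against 300.1 ± 80.8 CPM, a log2 fold change of -2.16 ± 0.24 with an adjusted p of 2.4e-05. PPP4C, a phosphatase subunit gene, had -3.47 ± 0.46, and the cell cycle regulator RGCC had -2.20 ± 0.43. CEBPB (-2.02), NCSTN of gamma-secretase (-1.97), the polarity gene LLGL1 (-1.84), CHST14 (-1.76) and HDHD5 (-1.76) followed. AC020978.7 was called lower too, with 0 counts in the 3 deletion libraries. Among the genes higher were SPATA5 (1.22 ± 0.25), RNF111 (1.04), MTRNR2L8 (1.01), PTPN4 (0.99), SNHG1 (0.76), EGFL7 (0.74) and MDM2, at 257 ± 42.7 against 156 ± 33.8 CPM (0.72 ± 0.14, adjusted p = 0.00728). MT-ND5 (0.67), MT-ATP8 (0.66) and ZNFX1 (0.63) completed the 10 largest rises. In the library left out of the deletion group, replicate 4, KLF2 was at 46.3 CPM and CD9 at 414 CPM. The number of calls fell to 60 when LDAH deletion replicate 3 was left out as well, 57 of them among the 212.

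**Figure D5:**
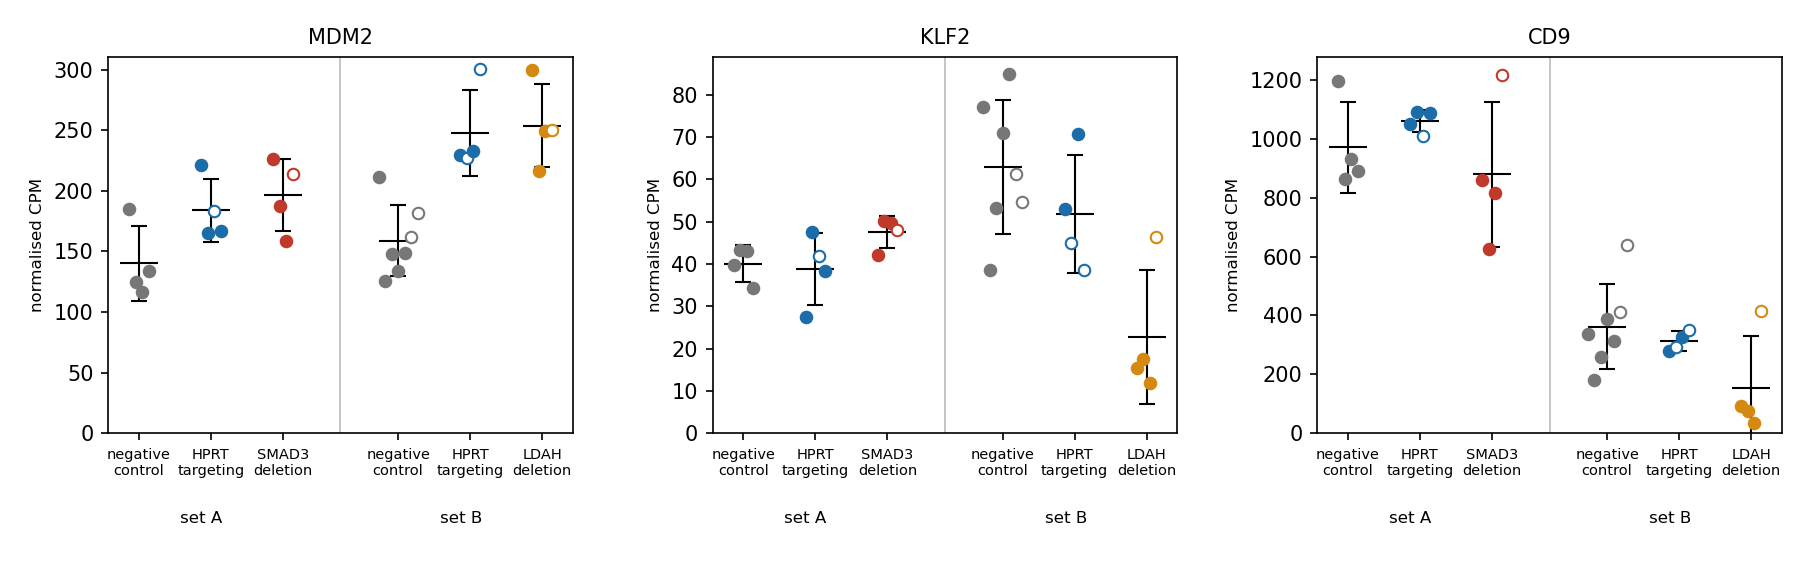
Normalised CPM of MDM2, KLF2 and CD9 in each library by group, with bars for the mean ± SD (the CD9 bar of the LDAH deletion extends under 0, outside the axis) and open symbols for the 7 libraries that stand apart. In the LDAH deletion, 3 libraries lie at 11.9 to 17.5 CPM of KLF2 and replicate 4 lies at 46.3 CPM.

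Comparison of each deletion with the HPRT-targeted libraries of its set asks what remains when both groups have a cleaved genome. The groups may differ in the number of cuts, since guide RNAs flanked the enhancer while a single guide targeted HPRT1. SMAD3 stood at 94.8 ± 15.1 CPM in its deletion against 124 ± 20.3 CPM (n = 4 and 4) in HPRT-targeted libraries, a log2 fold change of -0.39 ± 0.14 with an exact permutation p of 0.0857. No list passed camera: cholesterol genes had an adjusted p of 0.0560, and interferon-stimulated and mitochondrially encoded genes 0.0658. Over all 11467 genes edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0, with a smallest adjusted p of 0.352 and 669 genes at an unadjusted p under 0.05. With 1 library left out, the latter number ran from 460 (HPRT-targeted replicate 1) to 1581 (SMAD3 deletion replicate 4). DESeq2 called 17, 7 higher and 10 lower, and limma voom with sample quality weights called 5 lower, PTGR1, COX6C, EEF2, OVCA2 and MT-CO3. Without HPRT-targeted replicate 3 edgeR called 2, DPH1 and OVCA2, which share a locus and moved in opposite directions. These genes were chosen after their values were seen.

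With the 7 libraries left out and 3 remaining in each group, edgeR called 55 genes between SMAD3 deletion and HPRT targeting, 17 higher and 38 lower. Among the lower genes, 7 were mitochondrially encoded, such as MT-CO2 (-0.78), MT-ND4 (-0.74), MT-ND3 (-0.73), MT-ATP6 (-0.72), MT-CO3 (-0.71) and MT-CYB (-0.62), and the list's camera adjusted p was 6.8e-14, and 0.412 with an estimated correlation. TFRC, the transferrin receptor gene, had -0.88, CACNB3 -0.80, DCAF11 -0.68 and OVCA2 -1.26. Among the higher genes were MTRNR2L8 (0.97), the matrix protease gene MMP14 (0.62), DDX39B (0.61), CD70 (0.60), LIFR (0.60), HYOU1 (0.57), MARVELD1 (0.57) and SNX14 (0.55), besides DPH1 at 42.3 against 0.227 CPM. Proliferation genes were higher than in HPRT-targeted libraries, with a camera adjusted p of 0.0415, and 0.746 with an estimated correlation.

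LDAH stood at 7.32 ± 3.44 CPM in its deletion against 19.4 ± 10.5 CPM in HPRT-targeted libraries (n = 4 and 4), a log2 fold change of -1.39 ± 0.44 with an exact permutation p of 0.0857, and of -0.34 without the 7 libraries. Mitochondrially encoded genes were higher in 12 of 13, with a median of 0.30 and a camera adjusted p of 0.0122, and adjusted p = 0.976 with an estimated correlation. MT-ND5 had 0.70 ± 0.36, MT-ND2 0.37 ± 0.20, MT-CO3 0.41 ± 0.23 and MT-ATP8 0.78 ± 0.53, and 0 members passed edgeR's test. The group of HPRT-targeted libraries holds 2 that stand apart and the deletion group 1, and such libraries of set B had lower mitochondrially encoded genes. With the 7 left out MT-ND5 had 0.45 ± 0.21, MT-CO3 0.24 ± 0.17 and MT-ATP8 0.35 ± 0.21. In that fit the list still passed camera with the preset correlation, in the same direction. The list's adjusted p was 0.158 without LDAH deletion replicate 1, and 0.181 and 0.151 without HPRT-targeted replicates 2 and 3. CCN1 (-1.07) and the chemokine gene CXCL8 (-2.24), named after their values were seen, passed adjusted over their lists alone. Over all 11769 genes edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0, with a smallest adjusted p of 0.948 and 497 genes at an unadjusted p under 0.05. With 1 library left out, the latter number ran from 309 (LDAH deletion replicate 3) to 1103 (LDAH deletion replicate 4). DESeq2 and limma voom with sample quality weights called 0. EdgeR without the 7 libraries, with 3 and 2 left, called 77, 1 higher and 76 lower. The smallest p was that of AC020978.7, with 0 counts in the 3 deletion libraries. Among called genes with a mean CPM of at least 10, the largest falls were PPP4C (-3.57), RGCC (-2.64), CD9 (-2.20), LLGL1 (-2.12), KLF2 (-2.06), NCSTN (-1.996), GNB2 (-1.96), the actin-binding thymosin gene TMSB4X (-1.91), PLAU (-1.83) and SEC61G (-1.77). In that fit proliferation genes were higher than in HPRT-targeted libraries, with a camera adjusted p of 9.4e-07, and 0.786 with an estimated correlation.

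The last comparisons test differences between effects. For the HPRT effect in set B minus that in set A, no list passed camera, with a smallest adjusted p of 0.605. Of 12055 genes edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0, with 159 at an unadjusted p under 0.05. With 1 library left out, the latter number ran from 130 (negative control replicate 4 of set A) to 404 (HPRT-targeted replicate 3 of set B). DESeq2 called MATR3 and PTP4A1, limma voom with sample quality weights called 0, and edgeR called DPH1 without HPRT-targeted replicate 3 of set A and without the 7 libraries. These were named after their values were seen.

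For the SMAD3 deletion effect minus the LDAH deletion effect, mitochondrially encoded genes were lower in 11 of 13, with a median log2 difference of -0.53 and a camera adjusted p of 0.00131, and adjusted p = 0.751 with an estimated correlation. MT-CO3 had -0.54 ± 0.28, MT-ND4 -0.93 ± 0.48, MT-ND1 -0.54 ± 0.29 and MT-ATP6 -0.93 ± 0.55. EdgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 12055 genes, with a smallest adjusted p of 0.692 and 439 genes at an unadjusted p under 0.05. With 1 library left out, the latter number ran from 311 (SMAD3 deletion replicate 4) to 970 (LDAH deletion replicate 4). DESeq2 called 4, MATR3, PTP4A1, CRTC2 and RNF130, and limma voom with sample quality weights called KLF2. Adjusted over their lists alone, SUSD6 (0.88) and KLF2 (1.73) passed. Without LDAH deletion replicate 4 edgeR called KLF2, PPP4C, AC020978.7 and CD9. These were named after their values were seen. With the 7 libraries left out it called 68 genes, 66 higher and 2 lower, among them PPP4C (3.797), EHBP1-AS1 (2.59), KLF2 (2.38), RGCC (2.20), GNB2 (1.98), LLGL1 (1.93), CD9 (1.84), TMSB4X (1.81) and NCSTN (1.79).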

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

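The tests of depth, of cells of another type and of a single library were chosen before their results were seen, and all other tests in this part after. For cells of another type, the rule chosen beforehand counted a lower median over all markers in both sets against this explanation. The split by class of markers was not part of that rule.

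In 7 of 90 group and measure pairs tested, 1 library lay far from the others of its group, where chance gives about 1 in 20 groups, or 4.5. The total count was 3.43 M in LDAH deletion replicate 4, against 5.62 to 5.93 in the others, and 5.64 M in SMAD3 deletion replicate 4, against 7.43 to 7.49. Ribosomal protein genes took 16.5% of counts in LDAH deletion replicate 4, against 8.83% to 9.96%. The median correlation with the set was 0.945 in HPRT-targeted replicate 3 of set A, against 0.977 to 0.983, and 0.885 in SMAD3 deletion replicate 4, against 0.979 to 0.983. HPRT1 stood at 42.2 CPM in HPRT-targeted replicate 3 of set A, against 28.05 to 30.0, and at 69.2 CPM in SMAD3 deletion replicate 4, against 37.7 to 42.6. These 3 libraries are among the 7 that stand apart.

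The pattern of 7 libraries that stand apart is shared by the sets: across 11330 genes, their difference from the other libraries correlated between set A and set B (Pearson r = 0.80), genes not being independent replicates. Lower depth is argued against, since all 7 still stood apart after thinning to 3430481 counts. Cells of another type stay open: the median log2 difference of all their markers was -0.33 over 20 in set A and -0.40 over 22 in set B. This median joins classes that moved apart, with mesenchymal markers at -0.38 and -0.60 and epithelial and blood cell markers at 0.14 and 0.38. Only 7 of the 25 epithelial and blood cell markers were among the genes counted. Those tested were already expressed in the negative control libraries, at a mean log2 CPM of 5.62 in set A and 4.63 in set B. Loss of long transcripts may contribute: the difference fell with transcript length (Spearman rho = -0.31 in set A and -0.38 in set B, across genes), and the 10% of genes with the longest transcripts differed by a median of -0.37 and -0.73. Cells of another type were weighed as contamination, and no biological explanation was tested.

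The pattern of higher p53 targets and lower proliferation genes was weighed against the 7 libraries, and both lists passed camera without them in the HPRT comparison of each set, the largest adjusted p being 6.4e-08. With an estimated correlation neither passed within a set, with the 7 libraries or without them (0.167 for both lists in set A and 0.261 in set B without them). Neither passed the exact permutation within a set (0.183 in set A and 0.571 in set B without the 7 libraries). In set A that permutation can pass only if many of the 16 lists reach its smallest p together. In set B without the 7 libraries, all 16 would have to reach it. No conclusion is drawn from these failures. Chance values of the control libraries are argued against for p53 targets under HPRT targeting. The exact permutation p, adjusted over the 16 lists, was 0.00346 in both sets together. For proliferation genes chance values stay open, with 0.224 in that test. It gave 0.0145 for them without the 7 libraries, which were left out after seeing the data. A response to cleavage itself may be involved but stays open: the deletions lay at 1.19 (SMAD3) and 0.616 (LDAH) on a scale where the negative control is 0 and HPRT targeting 1, but both effects start from the same control. Among regroupings of the libraries with an HPRT effect as large, a share of 0.0121 of 991 in set A and 0.382 of 21393 in set B gave a deletion effect as large.

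The third pattern is the 212 genes changed in the LDAH deletion without the 7 libraries. A GC trend over all genes is argued against as the whole cause, since 183 of the 212 were still called with each library's GC trend removed. The median of the lower genes moved from -0.97 to -0.91. Fold changes of the genes tested had little trend with GC content to remove (Spearman rho = 0.00623). The lower calls had a median GC content of 51.1% and the higher calls 43.1%, against 47.7% for the genes tested. A GC effect on part of the genes is not excluded. A single library cannot be excluded, since leaving out replicate 3 kept 57 of the calls, while leaving out replicates 1 and 2 kept 164 and 144. A technical difference like that between the sets is not excluded: across 12153 genes the correlation with it was low (Pearson r = 0.0815), but 155 of the 212 had the same sign in both. An effect of the deletion may be involved, but LDAH itself was not called (-0.51), and the deletion libraries carry numbers apart from their controls.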

How the results depend on the processing

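The 7 libraries that stand apart were left out, list means permuted exactly, and neighbouring libraries blocked, as alternatives chosen after seeing the data; the others were planned, except that the estimated correlation was computed without precision weights. No value past its test changed sign under an alternative. For genes this was largely fixed in advance, since edgeR called none in any comparison with all libraries. Only gene values that passed under an alternative could have done so. Of 96 gene values, 14 that did not pass changed sign under at least 1 alternative, among them HS1BP3 (0.06) and LDAH in HPRT targeting of set B (from 0.64 to -0.16), both without the 7 libraries. The cause of a change was not tested unless stated.

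With camera's estimated correlation, which allows for members that vary together, the adjusted p was 0.329 for p53 targets, 0.505 for interferon-stimulated and 0.662 for proliferation genes in the SMAD3 deletion. In the LDAH deletion it was 0.250 for p53 targets, 0.250 for epithelial and blood cell markers, 0.415 for stress response and 0.415 for mitochondrially encoded genes. For HPRT targeting it was 0.238, 0.452 and 0.452 for p53, proliferation and cholesterol genes in set A, 0.122 and 0.976 for p53 and proliferation genes in set B, and 0.341 for proliferation genes in both sets. Mitochondrially encoded genes had 0.976 for the LDAH deletion against HPRT targeting and 0.751 for the difference of the deletions. Among the lists called with all libraries, p53 targets for HPRT targeting in both sets (0.00185) were the only one to pass.

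In the exact permutation of list means, the adjusted p was 0.457 for p53, interferon-stimulated and proliferation genes in the SMAD3 deletion (0.381, 0.392 and 0.381 without the 7 libraries). In the LDAH deletion it was 0.218 for p53 targets (0.381), 0.218 for epithelial and blood cell markers (0.190), 0.331 for stress response (0.214) and 0.331 for mitochondrially encoded genes (0.381). For HPRT targeting it was 0.152 for all 3 lists of set A (0.183), 0.242 and 0.776 for p53 and proliferation genes of set B (0.571 and 0.571), and 0.224 for proliferation genes in both sets. Mitochondrially encoded genes had 0.975 for the LDAH deletion against HPRT targeting (0.889). With 4 libraries against 4, this test can pass only if many of the 16 lists reach its smallest p together. The same holds within a set with the 7 left out. For HPRT targeting in set B without the 7, all 16 would have to reach it. For the LDAH deletion against HPRT targeting without the 7, 3 libraries against 2 are too few for it to pass at all. The 0.889 therefore decides nothing.

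DESeq2 called 14 genes for the SMAD3 deletion, 14 for the LDAH deletion, 17 for the SMAD3 deletion against HPRT targeting, 1 for HPRT targeting in set A, 1 in both sets, 2 for the difference of the HPRT effects and 4 for that of the deletions. Limma voom with sample quality weights called 2, 0, 5, 0, 6, 0 and 1 in the same order. It passed 1 near gene each for the SMAD3 deletion and HPRT targeting in set A, and gave 0.0668 for interferon-stimulated genes and 0.0940 for cholesterol genes. Without the 7 libraries the counts were 1, 212, 55, 1, 1, 1 and 68, besides 77 for the LDAH deletion against HPRT targeting. Of DESeq2's 14 for the LDAH deletion, 12 are among the 212. In the same fit 1 gene near SMAD3 passed, interferon-stimulated genes had 0.116 and epithelial and blood cell markers 0.0735. At a mean CPM of 10 or more, with fewer genes tested, these lists had 0.216 and 0.385. A fit of all 27 libraries called 9 genes for the LDAH deletion, 8 of them among the 212, and gave 0.0547 for proliferation genes in set B. A pooled control gave 0.257 for p53 targets in the LDAH deletion.

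Leaving out 1 library at a time gave adjusted p-values of 0.00111 to 0.0618 for cholesterol genes in set A, 0.00231 to 0.0950 for interferon-stimulated genes, and 4.5e-05 to 0.797 for proliferation genes in set B. In the LDAH deletion they were 1.6e-05 to 0.145 for p53 targets, 0.00296 to 0.3003 for epithelial and blood cell markers and 0.000149 to 0.0582 for mitochondrially encoded genes, and against HPRT targeting 0.000266 to 0.181 for the last. Calls ranged from 0 to 3 for the LDAH deletion, 0 to 2 for the SMAD3 deletion against HPRT targeting, 0 to 1 for the difference of the HPRT effects, 0 to 4 for that of the deletions, and 0 to 1 near SMAD3 and near HPRT1 in set A. For p53 targets in HPRT targeting of both sets, the range was 2.5e-13 to 1.6e-07.

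No paired analysis by replicate number was possible because the labels share none between groups and the numbers used here are accession order; the labels do not say that libraries with neighbouring numbers were handled together. Of 8 such pairs of HPRT-targeted and negative control libraries, 5 had a correlation over 0.1 between their deviations from the group means. Of 16 libraries, 8 correlated best with their own neighbour, and some such matches come by chance. In set B, pairs alike in whether they stand apart had 0.55, 0.66 and 0.58. The pair of HPRT-targeted replicate 2, which stands apart, and negative control replicate 2, which does not, had -0.38. Effects of neighbouring numbers and of standing apart are thus not separated. With the pairs as a block, edgeR called 0 genes for HPRT targeting in set A, in set B and in both sets, with 202, 333 and 515 genes at an unadjusted p under 0.05, against 257, 206 and 378, and no call of a list changed in these 3 comparisons. Thinning all libraries to a common total left 516 genes at an unadjusted p under 0.05 for the LDAH deletion, against 543, and 773 for the SMAD3 deletion, against 778; greater depth was not tested.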

Other observations

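All tests in this part were chosen after the results were seen. The number of genes at an unadjusted p under 0.05 was counted in other splits of the same libraries. As many genes as in the real SMAD3 deletion comparison, 778, came in 3 of 35 splits, the highest other split giving 1218. For the LDAH deletion, 543 genes came in 13 of 100 splits (highest other 3234), and for HPRT targeting 257 came in 16 of 35 in set A (456), 206 in 60 of 100 in set B (2096) and 378 in 33 of 100 in both sets (2190). Against HPRT-targeted libraries, 669 came in 15 of 35 for the SMAD3 deletion (2639) and 497 in 8 of 35 for the LDAH deletion (2730). For the differences, 159 came in 82 of 100 (1721) for the HPRT effects and 439 in 35 of 100 (3034) for the deletion effects. Chance is not excluded in any of these 9. Splits that gave several times the real count point to a structure of the samples that the groups do not follow.

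Without the 7 libraries, genes at an adjusted p under 0.05 were counted in the same way. For the LDAH deletion, 1 of 56 splits, the real one, gave 212 genes and the highest other gave 3. That share, 0.0179, is the smallest that 56 splits allow, and it was not adjusted over the counts tested here. Chance is thus argued against for that count, without being excluded. For the SMAD3 deletion, 8 of 35 splits gave at least the real count of 1 (highest other 18), and for HPRT targeting in set A 3 of 35 gave at least 1 (highest other 2), so chance is not excluded. For the SMAD3 deletion against HPRT targeting, 1 of 10 splits gave 55 genes (highest other 1), and the splits are too few for a share under 0.05.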
